A study of Homo sapiens with 8 samples.

How the data were processed

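Total RNA from 2 human lymphoma cell lines was measured on Affymetrix HuGene-1_1-st-v1 array strips, with 1 biotin-labelled sample per array, per the labels' protocols. The table held 8 arrays: 3 of KMH2 control cells, 3 of KMH2 cells given glucosamine for 24 h, and 2 of Ramos cells. Replicates within the 2 KMH2 groups were described as biological replicates in the series' design text. Whether the Ramos arrays are biological replicates was not given in the sources used here. The dose of glucosamine was not given in the sources used here.

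The values were log2 signals per probe set, as deposited by the authors, for 33297 probe sets on each array. The unit was read from the values, which ran from 1.935 to 13.213 with none missing. The summarization, background correction and normalization tools were not given in the sources used here, and scanner files and detection calls were not analysed here. Array medians over all probe sets lay between 5.62 and 5.68, and upper quartiles between 7.75 and 7.83, so the arrays were on a common scale although their distributions were not identical. Signals near the lower end include background of unknown size, which shrinks folds of weakly expressed genes. Levels of different probe sets were not read as differences in RNA amount between genes, and were compared only to choose 1 probe set per gene, to leave out dim probe sets and as a covariate. For arrays the number of replicates limits the precision. The median SD between replicates was 0.067 in KMH2 control, 0.08 in KMH2 glucosamine and 0.113 in Ramos, on the log2 scale.

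Probe sets were named through the platform annotation, dated 2016, which listed 21236 of them. Of these 19181 had 1 gene symbol and were tested, standing for 17958 genes. Another 2055 had several symbols and 12061 were unlisted. None of those was named. Entrez identifiers of 19143 tested probe sets matched the RefSeq gene table of GRCh38.p14, 38 did not, and 0 symbols changed. Coordinates were not printed, because the build behind the annotation was not given in the sources used here. For the 895 genes with several probe sets, the probe set with the highest mean was taken. Among genes called after glucosamine, 257 had several probe sets, and in 4 of them another probe set was called in the opposite direction. Probe sets of near-identical gene copies, such as the histone genes, can capture RNA of their relatives, so single histone genes are uncertain.

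Comparisons used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the probe sets tested, threshold 0.05). All adjusted p-values of single genes are from limma, and standard errors and 95% confidence intervals come from the same fits. The glucosamine comparison used the 6 KMH2 arrays. The cell-line comparison set Ramos against KMH2 control, with all 8 arrays in 3 groups sharing the spread. Titles, descriptions and source names call both Ramos arrays control, but the design text places 1 of the pair after glucosamine. The Ramos group was therefore defined by cell line alone, and no treatment was assigned to either array.

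Gene lists, 34 in number and fixed before the data were examined, were tested with limma's camera at its preset correlation of 0.01, with 1 probe set per gene and at least 5 measured genes, adjusted over the lists. Camera asks whether the genes of a list moved more than the other genes. For every list the members past the threshold were counted, adjusted over all probe sets and adjusted over the list alone. Some lists share members, among them SLC7A11 (ATF4 and NRF2 lists), STAT6 (Hodgkin and JAK-STAT lists), FAS (p53 and stress ligand lists) and XBP1 (ER and plasma cell lists).

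The genes named were also set by a rule fixed before the data were examined. For glucosamine these were the 12 largest rises and 12 largest falls among genes past the threshold whose glucosamine arrays all lay on the same side of all control arrays, the 3 members with the smallest p in each list past the threshold, 2 in every other list, and HSPA5, DDIT3, TXNIP, GFPT1, OGT and OGA. For the cell lines these were the 10 highest and 10 lowest genes, with the Ramos arrays on the same side of all 6 KMH2 arrays, the 4 members with the smallest p in the B-cell, germinal centre, Hodgkin, plasma cell and MHC class II lists, and MS4A1, CD79A, TNFRSF8 and CCL17. A further gene of that fixed set had no probe set of its own here and is not reported. Genes named outside this rule are said to have been chosen after their values were seen.

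Replicate numbers were shared between the KMH2 groups, and the design text describes replicates before and after treatment. Deviations from the group means correlated across probe sets between arrays of the same number (0.46, 0.23 and 0.23). Between arrays of different numbers the correlations ran from -0.37 to 0.25, and the negative ones all involved a replicate 1 array. Replicates 2 and 3 correlated as much across numbers (0.25 and 0.18) as within them (0.23 and 0.23). The correlations thus set the replicate 1 arrays apart but cannot tell whether replicates 2 and 3 are paired by number. The glucosamine comparison had no block, so any shift shared by arrays of the same number stays in its standard errors and p-values. Calls that changed in the fit with the replicate number as a block, which was an alternative, are given below. Ranges of adjusted p given for lists are over the alternatives tested with camera.

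Alternatives were the replicate block, quantile normalization, median centring (over the tested probe sets), leaving out dim probe sets (those under the median level), a trended and robust prior, array weights, other sets of arrays in the fit, all probe sets of the table, an estimated correlation or limma's fry for lists, the mean of a gene's probe sets, the mean of both KMH2 groups as the reference for Ramos, and leaving out each array in turn. Chosen after seeing the data were leaving out both KMH2 replicate 1 arrays, and median centring (both comparisons) and quantile normalization (Ramos) for the lists.

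The code was tested on simulated data made from the real arrays' means and spread, with 200 changed probe sets among 19181. For the glucosamine comparison it recovered 66% of changes of 0.5 and 100% of changes of 1, 2 or 3 on the log2 scale, with 6 unchanged probe sets among 189 called. For the cell-line comparison it recovered 50%, 90%, 98% and 100% at these sizes, with 7 unchanged probe sets among 176 called. The simulated noise was independent between probe sets, and far fewer probe sets changed than were called in the real data. These rates therefore test the code and are not error rates of the real comparisons. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.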

Results

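Gene expression was measured in 2 human lymphoma cell lines on 8 whole-transcript arrays. KMH2 is a line from Hodgkin lymphoma, a cancer of B-cell origin whose tumour cells have lost much of the B-cell program. Ramos is a line from Burkitt lymphoma, a cancer of germinal centre B cells. The samples fell into 3 groups, KMH2 control (3 arrays), KMH2 after 24 h of glucosamine (3 arrays) and Ramos (2 arrays). Glucosamine is an amino sugar that cells phosphorylate and pass into the hexosamine pathway, which makes the sugar donor for N-glycans and O-GlcNAc. Because the labels and the series' design text disagree on whether 1 of the Ramos arrays came from treated cells, Ramos was described as a cell line only. Values are log2 signals, and each difference below is glucosamine minus control, or Ramos minus KMH2 control.

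The comparison of treated with untreated KMH2 cells addressed the transcriptional response of these lymphoma cells to glucosamine. After 24 h the steepest rise was that of ARRDC4 (probe set 7986350), a glucose-responsive arrestin-domain gene, which went from 5.66 ± 0.19 to 8.81 ± 0.02 on the log2 scale (SD, n = 3 per group), an 8.85-fold difference. INHBE, a subunit of activin E, rose 7.60-fold, SLC7A11, the cystine importer, rose 7.44-fold, and CTH, which makes cysteine from cystathionine, rose 6.32-fold. On the other side, DLEU2, a long non-coding RNA, fell 4.06-fold, the complement gene C5 fell 3.80-fold and the cytokine gene IL21 fell 3.66-fold. The other large rises were in TFPI (5.34-fold), HMOX1, the stress-induced haem oxygenase (4.98-fold), the peptide hormone gene SPX (4.91-fold), GDF15, a secreted stress cytokine (4.49-fold), IL1A (4.07-fold), the pseudogene NMRAL2P (4.04-fold), DDIT3, the stress transcription factor CHOP (3.53-fold), and BEST1 (3.01-fold). The other large falls were in the histone gene H2BC14 (3.66-fold), ACADSB, an enzyme of branched-chain amino acid breakdown (3.33-fold), LINC00467 (3.17-fold), UTS2B (3.00-fold), the microRNA gene MIR142 (2.78-fold), CCNE2, cyclin E2 (2.74-fold), the mitochondrial carrier gene SFXN2 (2.73-fold), DTD2 (2.65-fold) and EME1, part of an endonuclease of recombination (2.60-fold). Adjusted p for these 24 genes ran from 3.62e-07 (CTH) to 0.00306 (IL21).

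**Figure D1:**
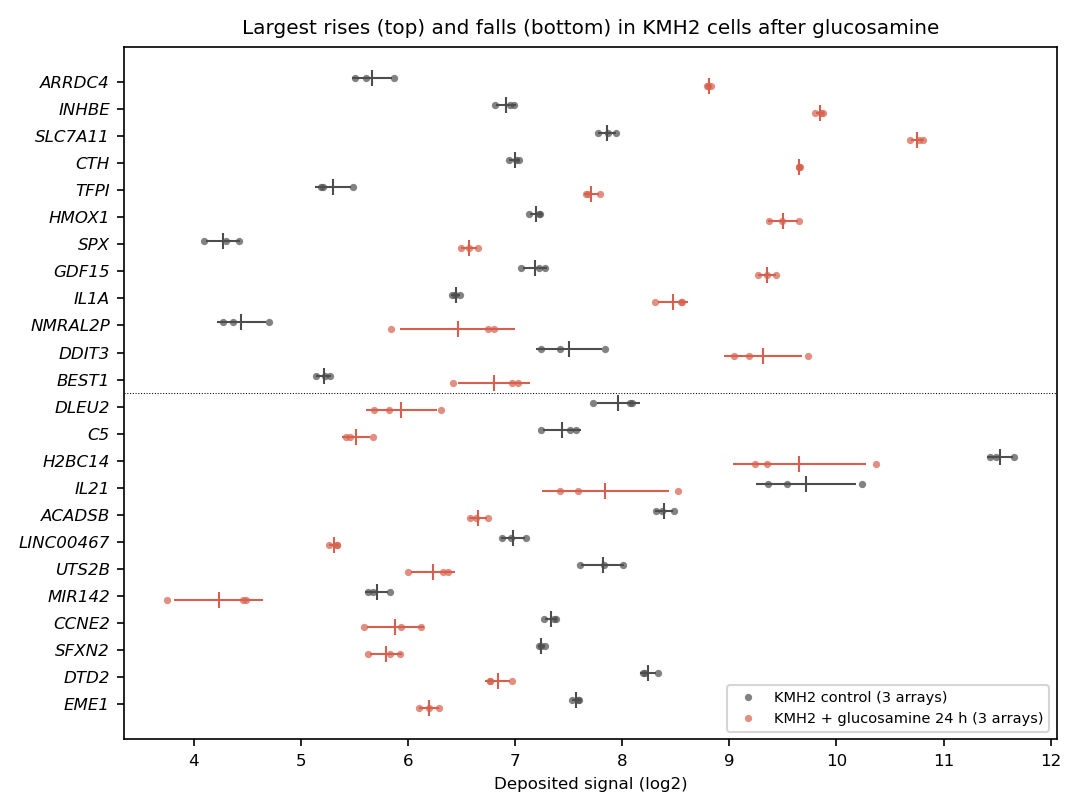
Deposited log2 signal (x axis) of the 12 genes with the largest rises and the 12 with the largest falls in KMH2 cells after glucosamine. Points are single arrays (3 per group), vertical ticks the means and horizontal lines 1 SD, and the genes were chosen among those with separated groups, such as ARRDC4 at 5.66 in control and 8.81 after glucosamine.

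Across the array 4956 of 19181 probe sets passed the threshold (25.8%), 2285 higher and 2671 lower after glucosamine. These stood for 2159 genes higher and 2533 lower. Most differences were small, with a median size of 0.37 on the log2 scale, and 75 probe sets rose and 84 fell by at least 2-fold. In 7842 of all tested probe sets (40.9%) the 3 glucosamine arrays lay outside the range of the 3 control arrays, a separation that chance gives to 10% of probe sets. The count was 2177 when all 8 arrays shared the estimate of spread, a fit in which 18 named genes lost their call (MCM10, UHRF1, POLR1A, RRP9, HK2, KIF23, NPC1, MSMO1, HMGCS1, CIITA, ERAP1, ACTA2, HSPE1, HSF1, CXCL10, IL7R, GFPT1 and OGA).

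Genes of the amino acid response rose most widely. Among 37 measured targets of ATF4, the transcription factor of the amino acid and integrated stress response, 29 rose, 1 fell and 7 did not pass the test (adjusted over the list alone, 30 and 1). The list moved up as a set (camera adjusted p = 2.62e-19), and it was the only list of the 34 still past the threshold with an estimated correlation (adjusted p = 0.0217 with an estimated correlation). Besides CTH and SLC7A11, PSAT1, an enzyme of serine synthesis, rose by 1.15 ± 0.05 (SE) on the log2 scale. The member that fell was PCK2 (-0.30), named here after its value was seen. Of 19 targets of NRF2, the regulator of antioxidant genes, 13 rose, 1 fell and 5 did not pass (adjusted over the list alone, 13 and 1), with camera adjusted p = 3.68e-07 (adjusted p = 0.0643 with an estimated correlation). They included SLC7A11 again, HMOX1, and GCLM, a subunit of the enzyme of glutathione synthesis (1.34 ± 0.07, SE). TALDO1 was the NRF2 target that fell (-0.24, chosen after its value was seen).

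Endoplasmic reticulum genes rose as well. The list holds chaperones and degradation factors, and also genes of protein transport and of the unfolded protein response. Of its 36 members 21 rose, 1 fell and 14 did not pass (adjusted over the list alone, 22 and 2). The camera test gave adjusted p = 2.11e-07 (adjusted p = 0.199 with an estimated correlation). DNAJB9, a chaperone, rose by 1.23, SEC24D, a coat protein of export vesicles, by 1.08, and XBP1, a transcription factor of the unfolded protein response, by 1.05. HSPA5, the main chaperone BiP, rose by 0.45 ± 0.06 (SE, adjusted p = 0.000891), from 11.70 to 12.14. The member that fell was the oxidase gene ERO1A (-0.28, chosen after its value was seen). The cytosolic heat shock list did not move as a set (17 members, 0 rose, 3 fell, adjusted p = 0.513), and HSPE1 fell by 0.36 and HSF1 by 0.24.

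Genes of the cell cycle fell, most widely those of DNA replication, while most mitosis and histone genes did not pass. In the list for DNA replication and the G1/S transition 28 of 32 members fell, 0 rose and 4 did not pass (adjusted over the list alone, 28 and 0). Camera gave adjusted p = 2.99e-15 (adjusted p = 0.158 with an estimated correlation). MCM10 fell by 0.88, UHRF1 by 0.79 and CCNE2 by 1.45 on the log2 scale. Of 29 mitosis genes 11 fell, 0 rose and 18 did not pass (adjusted over the list alone, 15 fell and 1 rose), with camera adjusted p = 1.86e-05 (adjusted p = 0.283 with an estimated correlation). HMMR fell by 1.37, the kinase gene AURKB by 0.51 and KIF23 by 0.37. Replication-dependent histone genes fell in 14 of 34 cases, 0 rose and 20 did not pass (adjusted over the list alone, 15 and 0), with camera adjusted p = 5.24e-05 (adjusted p = 0.576 with an estimated correlation). H3C1 fell by 1.26, H2BC14 by 1.87 and H3C10 by 0.83, and since the copies are near-identical, the single genes are uncertain. Of 22 p53 targets 12 rose, 1 fell and 9 did not pass (adjusted over the list alone, 15 and 1), with camera adjusted p = 2.16e-05 (adjusted p = 0.0643 with an estimated correlation). CCNG1 rose by 0.86, the death receptor gene FAS by 0.63 and TNFRSF10B, another death receptor, by 0.52, while the repair gene XPC fell by 0.71 (chosen after its value was seen).

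Ribosome assembly genes mostly fell, while fewer ribosomal protein genes passed and those rose, a difference between the lists that was not tested. In the list of ribosome biogenesis and MYC target genes 19 of 30 fell, 1 rose and 10 did not pass (adjusted over the list alone, 21 and 1), with camera adjusted p = 2.11e-07 (adjusted p = 0.0641 with an estimated correlation). UTP20 fell by 1.05, POLR1A, the large subunit of RNA polymerase I, by 0.61 and RRP9 by 0.52, and DDX21 rose by 0.16 (chosen after its value was seen). Cytosolic ribosomal protein and elongation factor genes rose in 11 of 38 cases, 0 fell and 27 did not pass (adjusted over the list alone, 11 and 0), by small amounts. Camera gave adjusted p = 0.000297 (adjusted p = 0.576 with an estimated correlation). EEF2, RPL12 and RPS13 each rose by 0.26, and RPS13 lost its call without control replicate 2 (adjusted p = 0.0523) or glucosamine replicate 3 (0.0503), over a range of 0.00123 to 0.0523 across its alternatives.

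Glycolysis genes fell. Of 19 members 13 fell, 1 rose and 5 did not pass (adjusted over the list alone, 14 and 1), with camera adjusted p = 3.68e-07 (adjusted p = 0.0643 with an estimated correlation). SLC2A1, the glucose transporter GLUT1, fell by 1.33 ± 0.08 (SE), hexokinase gene HK2 by 1.01 and LDHA, lactate dehydrogenase A, by 0.57. The related transporter gene SLC2A3 rose by 0.53 (chosen after its value was seen). The hexosamine and O-GlcNAc list did not pass as a set (17 members, 7 rose, 2 fell, adjusted p = 0.129). In it GFPT1, the rate-limiting enzyme of the pathway, rose by 0.33 (adjusted p = 0.00614) and NANS, of sialic acid synthesis, by 0.54, and HK2 fell. OGA, which removes O-GlcNAc, rose by 0.44 ± 0.11 (SE, adjusted p = 0.0212). That call was lost without control replicate 1 (0.0667), 2 (0.0624) or 3 (0.0604), without glucosamine replicate 2 (0.0599) or 3 (0.0768), and with all probe sets of the table (0.0535), over a range of 0.000483 to 0.453 across its alternatives. OGT, which adds O-GlcNAc, did not pass the test (0.23 ± 0.10, SE, adjusted p = 0.139). In the paired fit with a replicate block it did (adjusted p = 0.0410), as it did with array weights (0.00982). It also passed without glucosamine replicate 1 (0.00490) and without both replicate 1 arrays (0.00714), over a range of 0.00490 to 0.338 across its alternatives.

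Other metabolic lists did not pass as sets. Targets of the glucose sensors MondoA and ChREBP went both ways (15 members, 5 rose, 3 fell, adjusted p = 0.338). Among them ARRDC4 and KLF10 (1.43) rose, whereas TXNIP, a thioredoxin inhibitor that is a standard target of this pathway, was 4.51 ± 0.07 in control and 4.52 ± 0.05 after glucosamine (SD, n = 3 per group), with a 95% confidence interval of the difference from -0.12 to 0.15. Genes of N-glycan assembly split into 8 that rose and 10 that fell of 39 (adjusted p = 0.794), with ALG6 down by 0.87 (-0.87) and OSTC up by 0.51. Cholesterol synthesis genes had 8 rising and 4 falling of 18 (adjusted p = 0.0635), with MSMO1 up by 0.90 and HMGCS1 up by 0.64. That list passed with quantile normalization (0.0392), without glucosamine replicate 1 (0.0394) and without both replicate 1 arrays (0.0391), over a range of 0.0391 to 0.293. Hypoxia targets had 6 rising and 8 falling of 25 (adjusted p = 0.597), with DDIT4, an inhibitor of mTOR signalling, up by 0.97 and SLC2A1 down. Respiratory chain genes had 3 rising and 10 falling of 34 (adjusted p = 0.0617), with NDUFS4 up by 0.69 and ATP5MC1 at -0.56. They passed without control replicate 1 (0.0352) and without both replicate 1 arrays (0.0416), over a range of 0.0352 to 0.327. Glycosaminoglycan and hyaluronan genes had 5 rising and 4 falling of 30 (adjusted p = 0.937), with CSGALNACT2, of chondroitin sulfate synthesis, up by 1.00 and NAGLU at -0.31.

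Some lysosomal and surface ligand genes rose, although most members of both lists did not pass. Of 33 autophagy and lysosome genes 15 rose, 1 fell and 17 did not pass (adjusted over the list alone, 16 and 1), with camera adjusted p = 0.000297 (adjusted p = 0.0643 with an estimated correlation). WIPI1 rose by 1.05, NPC1, the lysosomal cholesterol exporter, by 0.88 and the autophagy receptor gene SQSTM1 by 0.67, and ATG7 fell by 0.17 (chosen after its value was seen). The list of NKG2D and surface stress ligands also holds the death receptor gene FAS. Of its 16 members 6 rose, 1 fell and 9 did not pass (adjusted over the list alone, 6 and 1), with camera adjusted p = 0.00917 (adjusted p = 0.173 with an estimated correlation). ULBP1 rose by 1.27 and MICA by 0.71, both ligands of the NK cell receptor NKG2D, and FAS rose as above, while CD47, which inhibits phagocytosis, fell by 0.68 (chosen after its value was seen).

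Markers of Hodgkin tumour cells fell in 11 of 31 cases, 3 rose and 17 did not pass (adjusted over the list alone, 13 and 4), with camera adjusted p = 0.0277 (adjusted p = 0.283 with an estimated correlation). GATA3 fell by 1.04, the transcription factor gene BATF3 by 0.87 and STAT6 by 0.83. Those that rose were CSF1R (0.54), and PDCD1LG2 (0.48) and ATF3 (0.44), the latter 2 chosen after their values were seen. The JAK-STAT list had 8 falling, 2 rising and 15 not passing of 25 (adjusted over the list alone, 12 and 2), with camera adjusted p = 0.0277 (adjusted p = 0.181 with an estimated correlation). STAT6 and BCL6 (-0.51) fell, and IL6ST, the shared receptor gp130, rose by 0.78, as did IL15RA (0.26, chosen after its value was seen). The Hodgkin list lost its call with quantile normalization (0.0538), without dim probe sets (0.0731) and without both replicate 1 arrays (0.058), over a range of 0.0184 to 0.283. The JAK-STAT list lost its call in the same settings (0.0593, 0.233 and 0.0528) and without glucosamine replicate 1 (0.0511), over a range of 0.0178 to 0.233.

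Several immune lists did not pass. Interferon-stimulated genes had 11 rising and 4 falling of 31 (adjusted p = 0.129), with IFI44 up by 0.94 and OAS2 up by 0.68. NF-kappaB targets had 4 rising and 5 falling of 35 (adjusted p = 0.513), with the chemokine genes CCL17 at -0.47 and CXCL10 at -0.45. MHC class I genes had 2 rising and 6 falling of 15 (adjusted p = 0.195), with ERAP1 at -0.47 and PSMB9 at -0.40. MHC class II genes had 1 rising and 5 falling of 15 (adjusted p = 0.0635), with RFXAP and CIITA both at -0.33. Germinal centre markers had 1 rising and 7 falling of 20 (adjusted p = 0.0635), with RGS13 at -0.82 and STMN1 at -0.58. In the paired fit with a replicate block the MHC class II list (0.0397) and the germinal centre list (0.0425) passed. The MHC class II list also passed without control replicate 2 (0.0296) or glucosamine replicate 1 (0.0432), over a range of 0.0296 to 0.576, and the germinal centre list passed without dim probe sets (0.0430), over a range of 0.0425 to 0.338. B-cell genes had 4 rising and 2 falling of 29 (adjusted p = 0.809), with the complement receptor gene CR2 at -1.13 and PAX5 at -0.37. Plasma cell markers had 4 rising and 1 falling of 14 (adjusted p = 0.343), with XBP1 as above and FKBP11 up by 0.53. Immediate early genes had 6 rising and 1 falling of 22 (adjusted p = 0.277), with JUN up by 1.40 and JUND up by 0.86.

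Few markers of other cell types passed the threshold, but PDGFRA (8.86 in KMH2 control) and CD14 (7.37) fell more than 2-fold. Some markers had low signals in KMH2 control, such as AHSP (3.96), IL7R (4.51) and EPB42 (4.79). A large fall of such genes could hardly be seen, so these lists say little about them. T-cell and NK markers had 0 rising and 2 falling of 25 (adjusted p = 0.597), namely CD4 (-0.28) and IL7R (-0.25), the latter not called without control replicate 1 (0.0630) or 3 (0.0773), without glucosamine replicate 2 (0.0638) or 3 (0.0592), or without both replicate 1 arrays (0.0569), over a range of 0.0133 to 0.173. Myeloid markers had 1 rising and 1 falling of 20 (adjusted p = 0.523), CSF1R up and CD14 at -1.08. Fibroblast and epithelial markers had 0 rising and 2 falling of 20 (adjusted p = 0.323), PDGFRA at -1.11 and ACTA2 at -0.43. Erythroid and platelet markers had 0 past the threshold among 10 (adjusted p = 0.687), with EPB42 at 0.15 (adjusted p = 0.241) and AHSP at 0.13 (adjusted p = 0.248). Adjusted over the list alone, counts of rises and falls among lists that did not pass became 4 and 14 in the respiratory chain, 10 and 4 in cholesterol synthesis, 2 and 8 in germinal centre, 1 and 6 in MHC class II, 3 and 7 in MHC class I, 0 and 2 in heat shock, 0 and 1 in T-cell and NK, and 10 and 11 in N-glycan genes, and were the same in the other 12. The mean and the median differed in sign for B-cell genes (-0.01 and 0.01) and for N-glycan genes (-0.02 and 0.01).

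**Figure D2:**
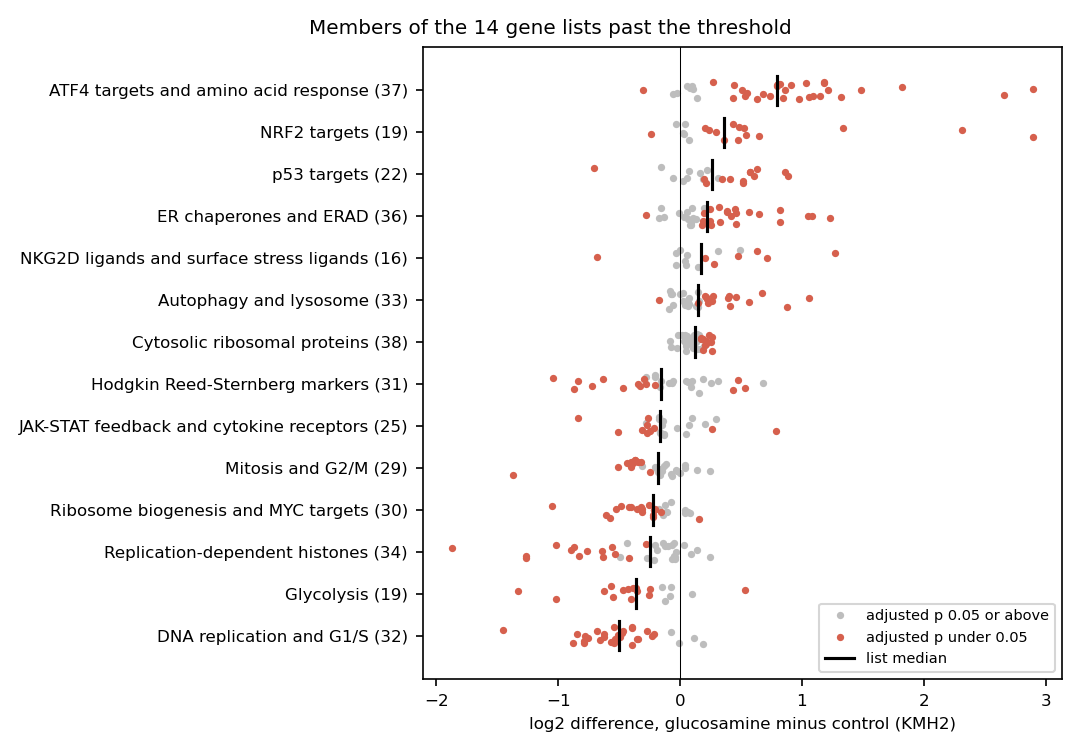
Log2 difference between glucosamine and control (x axis) of each member of the 14 lists past the threshold in KMH2, with the number of measured members in brackets. Points are genes, red where the adjusted p is under 0.05 and grey otherwise, black lines are list medians, and medians range from -0.50 for DNA replication genes to 0.80 for ATF4 targets.

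The comparison of Ramos with KMH2 control cells described how the 2 lines differ. Ramos had far higher signals of B-cell genes. JCHAIN, the joining chain of secreted antibodies, was 3.48 ± 0.05 (SD, n = 3) in KMH2 control and 11.17 and 10.41 in the 2 Ramos arrays, a 159-fold difference in the fit. MS4A1, which encodes CD20, differed by 151-fold and CD79A, a signalling chain of the B-cell receptor, by 65.8-fold. KMH2 in turn had far higher signals of SSX1, a cancer-testis antigen (248-fold), MMP12, a macrophage elastase (239-fold), and PRG4, lubricin (224-fold). Since low signals include background, such folds can be larger in the cells than on the array.

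The other genes highest in Ramos were CD180 (95.6-fold), PLAC8 (83.2-fold), SLAMF6 (74.8-fold), ST6GAL1, a sialyltransferase (73.7-fold), P2RX5 (73.3-fold), RASSF6 (71.8-fold) and CHI3L2 (64.8-fold). The other genes lowest in Ramos were GTSF1 (132-fold), CCND2, cyclin D2 (109-fold), S100A10 (108-fold), TIMP1, an inhibitor of metalloproteinases (102-fold), the chemokine gene CXCL10 (96.9-fold), PRXL2C (87.1-fold) and the small heat shock gene HSPB1 (80.9-fold). Background at low signals, such as RASSF6 in KMH2 control (2.99) and PRXL2C in Ramos (3.09 and 2.88), makes the order of these folds uncertain. Adjusted p for the 10 highest and 10 lowest genes was at most 1.00e-06 (ST6GAL1).

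In all 8408 of 19181 probe sets passed the threshold (43.8%), 4347 higher and 4061 lower in Ramos, with 1237 higher and 1621 lower by at least 2-fold. In 9269 of all tested probe sets (48.3%) the 2 Ramos arrays lay outside the range of the 6 KMH2 arrays, a separation that chance gives to 7.14% of probe sets. The median over the tested probe sets was 6.08 and 6.09 in the Ramos arrays and 6.22 to 6.23 in the KMH2 arrays, although medians over all probe sets were alike. Centring each array on this median moved the median difference of all probe sets from 0.06 to 0.20 on the log2 scale and gave 11924 probe sets, 72.1% of them higher in Ramos against 51.7%, so the balance of small differences depends on the scaling.

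Of the 34 lists 9 passed, 5 higher and 4 lower in Ramos. In the B-cell list 23 of 29 genes were higher, 2 lower and 4 did not pass (adjusted over the list alone, 25 and 2), with camera adjusted p = 1.58e-08 (adjusted p = 0.0831 with an estimated correlation). MS4A1, CD79A, CD180 and CD79B (4.94 on the log2 scale) led the list, and the exceptions were CD24 (-3.82) and CR2 (-1.08), chosen after their values were seen. Germinal centre and Burkitt markers were higher in 14 of 20 cases, lower in 1, and 5 did not pass (adjusted over the list alone, 15 and 1), with camera adjusted p = 6.63e-06 (adjusted p = 0.308 with an estimated correlation). CD38 was 5.92 higher, MME, which encodes CD10, 5.83, RGS13 3.78 and BCL6, the master regulator of germinal centre cells, 2.79, and EZH2 was the lower gene (-1.43, chosen after its value was seen).

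Hodgkin tumour cell markers were lower in Ramos in 24 of 31 cases, higher in 1, and 6 did not pass (adjusted over the list alone, 25 and 1), with camera adjusted p = 8.19e-13, a call that held with an estimated correlation (adjusted p = 0.0226 with an estimated correlation). TIMP1 differed by -6.67, MSC by -5.09, LGALS1, galectin-1, by -4.74 and BATF3 by -3.79. TNFRSF8, which encodes CD30, differed by -2.87 ± 0.13 (SE) and CCL17 by -0.73 ± 0.07 (SE, adjusted p = 4.64e-05). The gene higher in Ramos was CCL22 (2.10, chosen after its value was seen). NF-kappaB targets were lower in 25 of 35 cases, higher in 8, and 2 did not pass (adjusted over the list alone, 25 and 9), with camera adjusted p = 1.88e-05 (adjusted p = 0.0694 with an estimated correlation), and CXCL10 was among the lower genes. Interferon-stimulated genes were lower in 18 of 31 cases, higher in 4, and 9 did not pass (adjusted over the list alone, 19 and 4), with camera adjusted p = 1.58e-05, and held as well (adjusted p = 0.0486 with an estimated correlation). The 4 higher genes were PARP9 (2.65), IRF7 (1.08), IFI6 (0.59) and OAS2 (0.52), chosen after their values were seen. The JAK-STAT list had 12 lower and 3 higher of 25, and 10 did not pass (adjusted over the list alone, 13 and 3), with camera adjusted p = 0.00420 (adjusted p = 0.0943 with an estimated correlation). The 3 higher genes were BCL6, IL7R (2.07) and MYC (0.81), the latter 2 chosen after their values were seen.

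Plasma cell markers went both ways and did not pass as a set (14 members, 8 higher, 4 lower, the same counts adjusted over the list alone, adjusted p = 0.0855). JCHAIN, CD38 and MZB1 (3.42) were higher in Ramos and the transcription factor gene IRF4 was lower (-5.05). MHC class II genes had 4 higher and 3 lower of 15 (the same adjusted over the list alone, adjusted p = 0.920), with HLA-DOB at 0.95, HLA-DOA at 0.96, RFXANK at -0.72 and RFX5 at -0.57.

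The remaining 3 lists past the threshold were higher in Ramos, and lost their calls in other settings besides the estimated correlation. The B-cell, germinal centre, NF-kappaB and JAK-STAT lists lost theirs only with an estimated correlation. ATF4 targets were higher in 21 of 37 cases, lower in 3, and 13 did not pass (adjusted over the list alone, 24 and 3), with camera adjusted p = 0.00420 (adjusted p = 0.915 with an estimated correlation). The size rested unevenly on the 2 Ramos arrays, with a list mean of 0.93 on the log2 scale without Ramos replicate 1 (adjusted p = 3.76e-06) and 0.42 without Ramos replicate 2 (0.00653). The 3 lower genes were ATF5 (-2.41), CTH (-1.60) and ATF3 (-0.73), chosen after their values were seen. Respiratory chain genes were higher in 18 of 34 cases, lower in 4, and 12 did not pass (adjusted over the list alone, 18 and 5), with camera adjusted p = 0.0304 (adjusted p = 0.735 with an estimated correlation). The 4 lower genes were SDHC (-1.60), NDUFB6 (-1.18), COX7B (-0.49) and COX4I1 (-0.23), chosen after their values were seen. Cytosolic ribosomal protein genes were higher in 20 of 38 cases, lower in 3, and 15 did not pass (adjusted over the list alone, 20 and 4), with camera adjusted p = 0.0370 (adjusted p = 0.915 with an estimated correlation). The 3 lower genes were RPS23 (-0.52), RPS7 (-0.43) and RPL8 (-0.24), chosen after their values were seen. Against the mean of both KMH2 groups the ATF4 list (0.287, range 3.76e-06 to 0.915) and the ribosomal list (0.218, range 0.0183 to 0.915) lost their calls. That reference includes the glucosamine arrays, in which both lists were higher than in control (list means 0.805 and 0.116). The Ramos difference is thereby lowered, from 0.674 to 0.271 for ATF4 targets and from 0.17 to 0.112 for ribosomal genes. The ribosomal list also lost its call with quantile normalization (0.0873), without KMH2 control replicate 2 (0.0724) and without Ramos replicate 2 (0.212), and the respiratory chain list lost its call without Ramos replicate 1 (0.1301, range 0.00875 to 0.735). The other 23 lists had adjusted p of 0.0587 (MHC class I) or above.

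**Figure D3:**
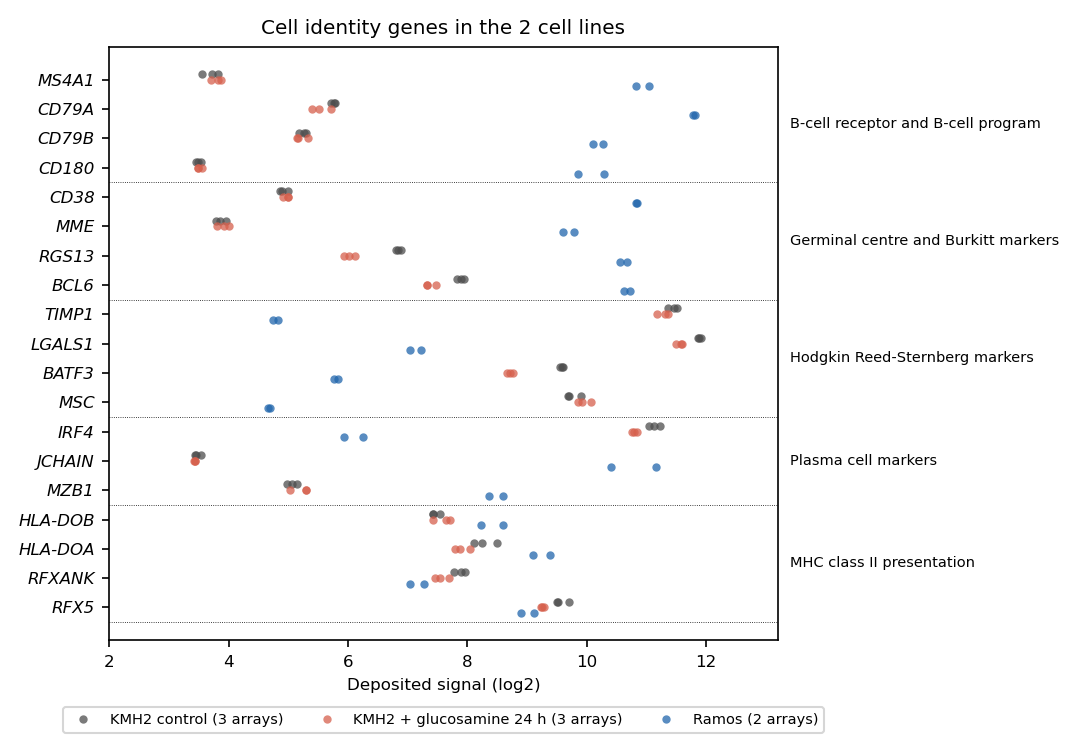
Deposited log2 signal (x axis) of the members with the smallest p in the B-cell, germinal centre, Hodgkin, plasma cell and MHC class II lists, set by list name at the right. Points are single arrays of KMH2 control (3), KMH2 after glucosamine (3) and Ramos (2), and MS4A1 lies at 11.04 and 10.83 in Ramos against a KMH2 control mean of 3.70.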

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

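The values in this part come from tests planned before their results were seen, and the choice to report probe sets outside the gene-level comparison came after.

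Probe sets without a gene of their own also changed in KMH2 cells after glucosamine. In a limma fit of all probe sets of the table, 386 of the 2055 that the annotation pairs with several genes passed the threshold (18.8%), 154 higher and 232 lower. Another 810 of the 12061 that it does not list passed (6.72%), 358 higher and 452 lower. In the same fit 20.6% of the probe sets with 1 gene passed. These signals stood out because the comparisons above named none of them and used them only in the alternative with all probe sets of the table. They may hold RNA of gene families, non-coding RNA or control probes, and no explanation of them was tested (the whole fit called 5140 probe sets).

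The 6 KMH2 arrays can be split into 3 and 3 in 10 ways. The real split gave 4956 probe sets, and 1 of the 10 splits, the real one, gave as many. The highest count of any other split was 0 with limma after adjustment, and at an unadjusted p under 0.05 the other splits gave from 136 to 776 probe sets, against 6931. Among them 3 other splits also part every replicate pair, and these gave 136, 209 and 281 at the unadjusted p. Each other split mixes control and glucosamine arrays, so the glucosamine difference enters its spread and lowers its counts. Those counts are therefore no fair reference for chance, and the splits are too few for a share under 0.05.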

How the results depend on the processing

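The alternatives were planned, apart from leaving out both KMH2 replicate 1 arrays and, for lists, median centring and (Ramos) quantile normalization. For glucosamine the count of 4956 probe sets was 5748 with the replicate block, which called 4876 of the 4956 and, besides the MHC class II and germinal centre lists and OGT, changed no other call of a list or named gene. It was 4772 to 6594 under scaling, filter, prior, array weight and all-probe-set alternatives, 5472 without both replicate 1 arrays, and 3600 to 5304 without any 1 array. With all 8 arrays in the fit it was 2177, because the difference between the 2 Ramos arrays then enters the spread. No probe set called here was called in the opposite direction under any of these. The 14 lists became 1 with an estimated correlation, 24 with fry, which does not compare a list with other genes, and 13 to 16 otherwise, 14 to 15 when an array was left out. Under fry the B-cell list passed as lower (mean difference -0.007, adjusted p = 0.0376), where camera had put it on the higher side, and the histone list did not pass (0.0978). The cause was not tested.

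For Ramos the 8408 probe sets ranged from 6136 (dim probe sets left out) to 11924 (median centring). The 6136 were out of only 9591 tested, and 5992 of the 8408 were called again there. Against the mean of both KMH2 groups the count was 8894, with 7794 of the 8408 called again. Without any 1 KMH2 control array it was 7035 to 7321. The 9 lists became 2 with an estimated correlation, and 8 to 12 otherwise. Without an array they were 8 to 13. Without Ramos replicate 1, cholesterol (0.000122), DNA replication (5.75e-06), NRF2 (0.0324), heat shock (0.0355) and ribosome biogenesis (0.00194) lists also passed, cholesterol and NRF2 as higher and the others as lower in Ramos. These rest on the array kept, since without Ramos replicate 1 or 2 the list means were 0.95 or -0.014 (cholesterol), -0.794 or 0.053 (DNA replication), 0.588 or 0.22 (NRF2), -0.733 or -0.35 (heat shock) and -0.439 or 0.132 (ribosome biogenesis). Other lists gained were glycosaminoglycan without Ramos replicate 2 (0.0270) and with median centring (0.0302), MHC class I (0.0332) and DNA replication (0.0241) with median centring, and mitosis against the mean of both KMH2 groups (0.0444). Over their alternatives these 8 lists reached from 5.75e-06 to 0.963. The mean of both KMH2 groups includes the glucosamine arrays, in which mitosis genes were lower (list mean -0.224), which raises the Ramos difference of that list. A lone Ramos array was assumed to vary like the other groups. Dim probe sets could not be told from background without detection calls. Leaving out dim probe sets left the erythroid list with too few genes to test, and 11 named genes of the glucosamine comparison and 10 of the Ramos comparison were not tested in that setting.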

Other observations

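The gene lists in the next 3 paragraphs, the tests of them without genes already named or listed, and the tests on the Ramos arrays, on TXNIP and CHAC1 and on replication against mitosis genes were chosen after the results were seen, while the test with control signal as a covariate and the first test of cytosolic against mitochondrial tRNA synthetases were set before their own results were seen.

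Mitochondrial enzymes that break down branched-chain amino acids fell in KMH2 after glucosamine, in 10 of 14 cases with 1 rising. Genes of fatty acid oxidation and electron transfer fell in 5 of 14 cases, and the other 9, among them CPT1A (0.07, adjusted p = 0.478), did not pass. CPT1A (4.82 in KMH2 control) and ACADL (3.44) had low signals, where a fall could hardly be seen. Of the 28 genes together 15 fell, 1 rose and 12 did not pass (camera adjusted p = 9.87e-08, over 6 added lists, and adjusted p = 0.0149 with an estimated correlation). As these lists were drawn up with the results in view, their p-values are descriptive. Without ACADSB, which had been named above, 14 of 27 fell (7.05e-07, and 0.0480 with an estimated correlation). BCKDHB, of the branched-chain ketoacid dehydrogenase, fell by 1.15, CPT2, which hands fatty acids to oxidation, fell by 1.04 and BCAT2, the mitochondrial aminotransferase for branched-chain amino acids, fell by 0.91, besides ACADSB above. Genes of homologous recombination and the Fanconi pathway fell in 17 of 23 cases, 1 rose and 5 did not pass (camera adjusted p = 3.51e-09, and adjusted p = 0.0815 with an estimated correlation), and without EME1 16 of 22 fell (3.13e-08, and 0.109 with an estimated correlation). EXO1 fell by 1.34 and FANCF by 0.98, and BLM rose by 0.43.

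Amino acid transporter genes rose in 11 of 17 cases, 1 fell and 5 did not pass (camera adjusted p = 3.92e-07, and adjusted p = 0.0149 with an estimated correlation), with 6 of the 17 held by the lists above. Without those 6 genes 6 of 11 rose (0.00652, and 0.0869 with an estimated correlation). SLC1A4 rose by 1.32, SLC3A2 by 1.09 and SLC7A5 by 1.03, and SLC38A5 fell by 0.35. Secreted cytokines and growth factors did not move as a set (39 genes, 5 rose, 4 fell, 30 did not pass, adjusted p = 0.237). Some of them had low signals in KMH2 control, such as IL18 (2.77) and IL2 (2.99), where a fall could hardly be seen. The large differences were mostly in genes already named (INHBE, GDF15, IL1A and IL21) or held by another list (VEGFA, 0.91), and without such genes 1 rose and 3 fell of 30 (adjusted p = 0.941), with IL12B at -1.36.

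Cytosolic tRNA synthetase genes rose in 10 of 19 cases, 2 fell and 7 did not pass (camera adjusted p = 0.000197, and adjusted p = 0.0284 with an estimated correlation). Mitochondrial ones fell in 8 of 15 cases, 2 rose and 5 did not pass (camera adjusted p = 0.00759, and adjusted p = 0.0652 with an estimated correlation). The mean log2 difference of cytosolic genes was 0.391 above that of mitochondrial genes (permutation p = 0.003, 100000 permutations over genes, which are not independent replicates). Of the 19 cytosolic genes 6 are in the ATF4 list, and without them the gap was 0.251 (permutation p = 0.054), 5 of 13 rose, 2 fell and the list did not pass (adjusted p = 0.115). What argues against a rise of both kinds alike is thus the fall of the mitochondrial genes. A hypothesis is that the amino acid response may account for the cytosolic part, and this was not tested further.

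The 2 Ramos arrays differed more than replicates of KMH2 did. The SD of their log2 difference over probe sets was 0.381, against 0.115 to 0.208 for the 6 pairs of KMH2 replicates, which argues against array noise of that size, and 0.289 to 0.321 between a KMH2 control and a KMH2 glucosamine array. Their difference correlated with the KMH2 glucosamine response across probe sets with a size of 0.449, against at most 0.189 for KMH2 replicate pairs set against a response from the other arrays (genes are not independent replicates). For each KMH2 pair that response rested on the single array left in the pair's group. The pairs also differed less, and both points can lower the size reached, so 0.189 is not a like reference. A treatment difference between the 2 Ramos arrays, as the design text has it, is a candidate explanation, and other differences between the cultures, such as density or nutrient supply, could move the same genes and stay open. No treatment was assigned to either array, every Ramos value above averages over this pair of unlike arrays, and no difference between the lines in the response was tested.

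Within KMH2 the targets of stress and sugar sensing parted. ARRDC4 rose by 3.15 on the log2 scale, but TXNIP, its relative under the same sensors, differed by 0.01 (adjusted p = 0.900), and among ATF4 targets CHAC1, a target that degrades glutathione, differed by -0.03 (adjusted p = 0.843). Probe sets that do not respond to these transcripts are argued against, since both lay at least 2.85 above their KMH2 control mean in each Ramos array. A hypothesis is that the 2 genes may be shut off in KMH2 cells, for which no test was possible with expression values alone.

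Replication genes fell more than mitosis genes. The means of the 2 lists differed by -0.271 on the log2 scale (permutation p = 0.00069, 100000 permutations over genes, which are not independent replicates). With each gene taken relative to its mean over the control arrays, which centres those on 0, the difference was -0.399, -0.211 and -0.205 in single glucosamine arrays, and control arrays spread from -0.014 to 0.012, which argues against a fall of all cell-cycle genes alike. With the control signal as a covariate the lists differed by -0.275 (permutation p = 0.00064), which argues against a difference in signal level. A shift of cells out of S phase, or fewer cycling cells with a slower decay of mitotic transcripts, could each give this and stay open, as no cell counts or cycle profiles were analysed here.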
